A study of Mus musculus with 6 samples.

How the data were processed

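Gene expression was measured in ovaries of 20-week-old female mice of the C57BL/6J strain, 3 wild type and 3 lacking selenium-binding protein 1 (SeBP1 in the labels, gene symbol Selenbp1). Each of the 6 samples was hybridised to a single-colour Agilent whole-genome mouse oligonucleotide array after labelling of its RNA with the dye Cy3, per the labels' protocols. The samples were grouped by the genotype given in the labels. Their names carry different numbers in each group, and nothing in the labels says outright that each array is a separate animal, so that p-values measure the spread between these samples.

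The deposited scanner files hold spot intensity on a linear scale from Agilent Feature Extraction 10.7.1.1, per the file headers. The processed intensity is background-subtracted and detrended within each array, and low values are replaced by surrogates, per the file headers, with no normalization between arrays. Probe coordinates follow mouse build mm9, per the file headers. The deposited series table also holds intensity, with a single value per probe and array. All 6 of its columns had the same median of 119.8 and followed the scanner values of their own array with a Spearman correlation of at least 0.9999 across probes, so its scale is linear and its arrays share a distribution, as quantile normalization gives. It is not centred by gene, and how it was made is not given in the sources used here. It served as an alternative.

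Each array held 43020 spots that were not controls, for 39429 probes, of which 399 had 10 spots each. Spots marked as outliers by the scanner software, between 192 and 459 per array, were left out, and the spots of a probe were averaged. No spot was saturated. The main values were log2 of the processed intensity minus the 75th percentile of it on that array. A probe was kept where it was well above background on all 3 arrays of at least 1 genotype, which left 24415 probes for 19412 genes. A probe with no array of a group well above background has only a bound there. Its fold is then given as "at least", from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value well above background on that array. Precision is limited by the number of arrays.

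Probes were named through the RefSeq accession in the files and a gene table of assembly GRCm38, used for names only. This named 26412 probes by accession, 3854 by symbol and 735 by an older symbol, and 8428 kept the name in the file. Where a gene had several kept probes, the probe with the highest mean log2 value stood for it in gene lists and among named genes.

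Knockout and wild type were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, on all 6 arrays with genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all kept probes. 25 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list and with fry. The lists cover selenium and sulfur metabolism, redox and AHR genes, steroid and cholesterol genes, ovarian cell types, other tissues that a dissected ovary can carry, blood and immune cells, proliferation, respiration and the neighbours of Selenbp1. Several lists share members, such as Hsd17b7, Cyp11a1 and Star. Of the genes listed, 3 had no probe under their name (Insl3, Obox2 and Selenbp2). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

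The named genes followed a rule set before the data were examined, as were the lists, the alternatives and the tests of genes and lists. Tests of explanations for single patterns were set after those patterns were seen. Selenbp1 and Selenbp2 were always to be named. In each direction, 12 genes were named, first those past the threshold with no overlap between the groups by size of change, then those with the smallest unadjusted p, leaving out clone and predicted names. From each list came up to 4 members past the threshold or, with none past it, the 2 with the smallest p. The value of 1 gene that this rule named is not reported here. Because Selenbp2 has no probe under its name, the probe described in the files as similar to it was added.

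The arrays lay on 2 slides, which were also scanned separately. Slide 1 held wild type replicates 1 and 2, and slide 2 held wild type replicate 3 and the 3 knockouts. With slide as a block, the genotype difference therefore rests on slide 2 and equals the difference there between the knockouts and wild type replicate 3. The p-values of that fit hold no spread between wild types on slide 2. They rest on the spread between wild type replicates 1 and 2 and among the knockouts. Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited series table, no filter or a stricter filter on background, slide as a fixed or a random block, the shared slide alone, the replicate number as a block, a trended robust variance, array weights, a 2-fold minimum, the mean over a gene's probes, and leaving out each array in turn.

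The gene test was tested on simulated data for this comparison. In 20 simulated sets of 24415 probes with 200 changed, it recovered 59% of changes of log2 1, 93.9% of log2 2 and 98% of log2 3, and 5.19% of its calls were false. The simulated noise was independent between probes, and 200 changes ease the adjusted threshold more than 1 called gene does. These rates may therefore overstate what the test finds on the real arrays. Of 20 sets with no change, 2 gave a call. The list test, run 100 times on simulated lists with the estimated correlations and no genotype effect, called a median of 7 lists at the preset correlation and 0 at an estimated correlation. A list of independent genes shifted by 0.3 on the log2 scale was called in 20 of 20 runs at the preset correlation and in 18 at the estimated correlation. No list of genes that vary together was shifted. How often a shift in such a list would be called at an estimated correlation was therefore not tested.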

Results

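RNA from 3 wild-type and 3 Selenbp1 knockout ovaries was profiled to ask how loss of this gene affects expression in the ovary. Selenbp1 encodes a selenium-binding protein that acts as a methanethiol oxidase. Between 61.6% and 69.3% of the spots were well above background, with the lowest share in wild type replicate 3 and the highest in knockout replicate 3. The 75th percentile of the processed intensity lay between 1309 and 1759. Spots of the same probe varied most in wild type replicate 3, with a median coefficient of variation of 13.2% against 3.22% to 6.94% on the other arrays. Across probes, which are not independent replicates, Pearson's r was 0.983 to 0.993 within wild type, 0.980 to 0.990 within the knockout and 0.977 to 0.991 between genotypes.

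Selenbp1 itself was 6.72-fold lower in the knockout ovaries, and all 3 knockouts lay far below all 3 wild types. Its log2 signal, relative to the 75th percentile of each array, was 2.60 ± 0.08 (SD, n = 3) in wild type and -0.15 ± 0.20 (SD, n = 3) in the knockout. The log2 difference was -2.75 with a standard error of 0.13 (limma, adjusted p = 0.0104). The region read by the probe lies on chromosome 3 at 94748621 to 94748680 (mm9). Its place in the exons was not worked out here, and the labels do not give the deleted part, so the probe may lie outside it. Signal in the knockouts stayed well above background on all 3 arrays, at 1287 to 1519 intensity units against 7894 to 11236 in wild type. The files assign the same probe to a Selenbp2 transcript too, a near-identical neighbour, so the source of the remaining signal is uncertain. A separate probe that the files describe as similar to Selenbp2, LOC100045064, on chromosome 3 at 94506773 to 94506832, differed by 0.20 with a standard error of 0.24 (adjusted p = 1.00) and by -0.055 without knockout replicate 2. With slide as a block the Selenbp1 difference was -2.74 (adjusted p = 0.0792), and on the shared slide alone it was -2.74 (adjusted p = 0.347). Leaving out wild type replicate 1, wild type replicate 2, knockout replicate 1 or knockout replicate 3 gave adjusted p values of 0.167, 0.144, 0.141 and 0.0631, with differences between -2.64 and -2.78.

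Beyond Selenbp1, no gene passed the threshold in either direction. With limma, 1 gene was lower and 0 were higher at an adjusted p under 0.05, and the second smallest adjusted p was 0.336. At an unadjusted p under 0.05 there were 964 probes, 538 higher and 426 lower, or 3.95% of the 24415 tested, where 1221 would be expected by chance. The count was above that with slide as a block (2389), on the shared slide alone (1604), with array weights (3769), without wild type replicate 3 (1561) and without knockout replicate 2 (1415). Over the other splits of the 6 arrays into 3 and 3, the number of such probes ran from 240 to 3812. A count below or above 1221 therefore says little by itself. The groups did not overlap in 8.58% of probes, and chance gives 10%. The count of genes was 0 with slide as a block, 0 without wild type replicate 1, wild type replicate 2, knockout replicate 1 or knockout replicate 3, and 19 without wild type replicate 3, of which 18 were lower in the knockout. Array weights gave 6 genes.

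**Figure D1:**
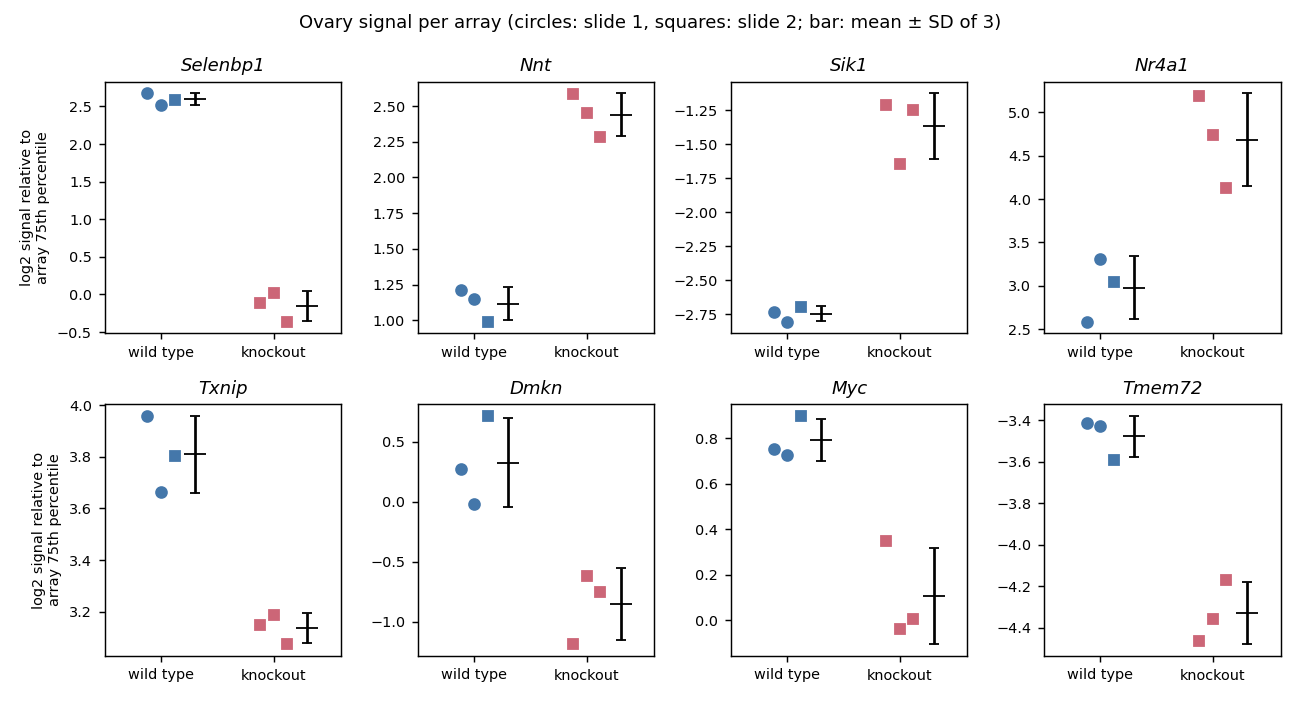
Signal of 8 genes on each array, as log2 relative to the 75th percentile of that array, in wild type and knockout ovaries. Circles are arrays on slide 1, squares are arrays on slide 2, and the bar gives the mean and SD of 3 arrays. Selenbp1 lay between 2.53 and 2.68 in wild type and between -0.37 and 0.02 in the knockouts, and it alone passed the threshold.

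Among the 12 higher genes with the smallest p, none past the threshold, was Nnt, which encodes the mitochondrial nicotinamide nucleotide transhydrogenase. Its log2 signal was 1.12 ± 0.12 (SD, n = 3) in wild type and 2.44 ± 0.15 (SD, n = 3) in the knockout, a difference of 1.32 with a standard error of 0.13 (limma, adjusted p = 0.336). The Nnt probe lies on chromosome 13 at 120124335 to 120124394 (mm9), and a second Nnt probe was not well above background on any array. Sik1, a salt-inducible kinase, differed by 1.38 with a standard error of 0.15 (adjusted p = 0.336). The nuclear receptor gene Nr4a1 differed by 1.71, with a standard error of 0.31. Serpinb1c differed by 1.75 but was well above background on only 1 of the 3 wild-type arrays, and Notch1, which encodes a signalling receptor, differed by 1.31 and was well above background on 2 of them. Smad7, an inhibitor of TGF-beta signalling, and Cry1, a repressor in the circadian clock, differed by 0.62 and 0.58. The remaining 5 were Pnma2 at 1.24, Rasgef1b at 1.23, Tmem52 at 0.71, Nkx1-1 at 0.53 and Tcf7l1 at 0.51.

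Of the lower genes with the smallest p, 11 besides Selenbp1 were named, and none passed the threshold. Txnip, which encodes a thioredoxin-interacting protein, was lower by both of its probes, with log2 differences of -0.67 (standard error 0.12) and -0.60 (standard error 0.16). Myc, a proliferation-linked transcription factor, differed by -0.69 with a standard error of 0.14. Dmkn, a secreted protein of epithelia, differed by -1.17 and -1.19 on its 2 probes. Agr2, a protein disulfide isomerase of secretory epithelia, was well above background on all 3 wild-type arrays and on 0 knockout arrays and was at least 5.35-fold lower (adjusted p = 1.00). Olfr213 had the same pattern and was at least 3.40-fold lower. The others were Tmem72 at -0.85, Strn at -0.79, Ces1d at -0.72, Hspb9 at -0.68, Cacna1i at -0.67 and Myo5b at -0.63. On the slide that held both genotypes, the difference was 1.45 for Nnt, 1.33 for Sik1, 1.64 for Nr4a1, -0.67 and -0.35 for the 2 probes of Txnip, -0.79 for Myc and -1.57 and -1.45 for the 2 probes of Dmkn. The groups did not overlap in any of the 23 genes named besides Selenbp1, which by itself fixes their direction on that slide.

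Selenium, sulfur and redox genes showed no called change. Of 28 measured selenoprotein and selenium-handling genes, 21 were lower and 7 higher, with a median log2 difference of -0.034 (-0.036 with slide as a block) and an adjusted p of 0.263 by camera. The members with the smallest p were Selenot at -0.25 and Dio3, which encodes a deiodinase, at 0.48, or 0.23 without knockout replicate 2. Of 20 sulfur amino acid and sulfide genes, 11 were lower, with a median of -0.020 (0.10 with slide as a block, 0.0025 with the deposited series table, 0.025 without wild type replicate 1), and camera gave an adjusted p of 0.560. Got1 differed by -0.22 and Cdo1, the cysteine dioxygenase, by -0.51, or 0.075 with slide as a block. In the NRF2 and glutathione list 18 of 27 genes were lower, with a median of -0.061 (-0.070 with slide as a block, 0.0043 with array weights) and an adjusted p of 0.254. Gsta1, a glutathione transferase, was at 0.82, or 0.51 without knockout replicate 3, and Gsr, the glutathione reductase, was at -0.17. Of 11 genes of the AHR battery, 7 were higher, with a median of 0.058 (0.057 with slide as a block) and an adjusted p of 0.275, and Ahrr, the AHR repressor, was at 0.30, or 0.090 without wild type replicate 3. In these 4 lists 0 members passed the threshold over all probes and 0 when adjusted over the list alone.

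Genes of cholesterol synthesis and uptake were called lower at the preset correlation only, and their arrays overlapped between genotypes. All 24 measured members were lower in the knockout mean, with a median log2 difference of -0.39 (-1.20 with slide as a block), and camera at its preset correlation gave an adjusted p of 0.000398. With an estimated correlation the adjusted p was 0.693. Sc5d, a late step of the pathway, was at -1.05 with a standard error of 0.33. No member passed the threshold, over all probes or adjusted over the list alone. The list median per array, relative to the mean of each gene, was -0.38, 0.036 and 1.01 in wild type replicates 1 to 3 and 0.22, -0.66 and -0.26 in knockout replicates 1 to 3. Without wild type replicate 3 the adjusted p was 0.825, and without knockout replicate 2 it was 0.222. The call was also lost with array weights (adjusted p = 0.315). It was kept in 15 of the 18 alternatives run at the preset correlation. Of 18 steroidogenic genes 11 were lower, with a median of -0.069 (-0.33 with slide as a block, 0.0099 with array weights) and an adjusted p of 0.560. Cyp17a1, the enzyme of androgen synthesis, was at 0.63 with a standard error of 0.48, or 0.22 without wild type replicate 3. Tspo was at -0.34 with a standard error of 0.26, or -0.12 without wild type replicate 3 and -0.13 without knockout replicate 2.

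**Figure D2:**
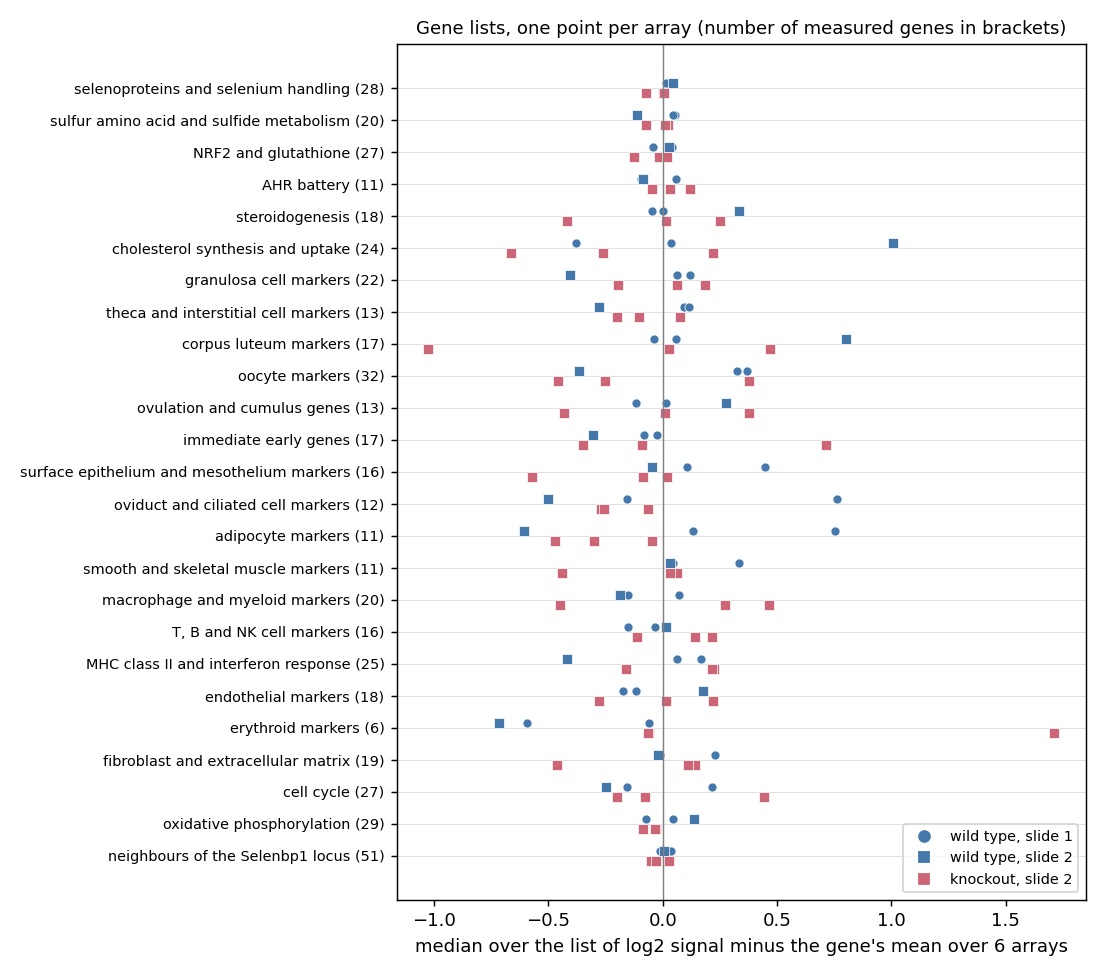
Median over each gene list of the log2 signal minus the gene's mean over 6 arrays, with each point an array and the number of measured genes in brackets. Circles are slide 1 and squares slide 2. Within a genotype the arrays spread widely in many lists, as for corpus luteum markers at 0.80 in wild type replicate 3, 0.47 in knockout replicate 1 and -1.02 in knockout replicate 2, while selenoprotein genes stayed between -0.071 and 0.044.

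No list of ovarian cell type markers was called with an estimated correlation. With slide as a block the granulosa median stayed higher and the corpus luteum median lower, while the oocyte and theca medians changed sign. Of 32 oocyte markers 30 were lower, with a median of -0.21 and a camera adjusted p of 0.0235. The list median per array, relative to the mean of each gene, was 0.33, 0.37 and -0.36 in wild type replicates 1 to 3. In knockout replicates 1 to 3 it was -0.25, 0.38 and -0.46, so the genotypes overlapped. With an estimated correlation the adjusted p was 0.693. With slide as a block, which sets the knockouts against wild type replicate 3 alone, the oocyte median was 0.27, of the opposite sign. At the preset correlation camera then called the oocyte list higher, so its call depended on the setting in direction too. Sohlh2 was at -0.28 and Sohlh1 at -0.50, both transcription factors of early oocytes, and Sohlh1 was at 0.047 with slide as a block. Without wild type replicate 1, wild type replicate 2, knockout replicate 1 or knockout replicate 3 the oocyte list had adjusted p values of 0.514, 0.262, 0.124 and 0.719, and its call was also lost with no filter on background (0.123) and slide as a random block (0.325). Granulosa cell markers were higher in 15 of 22, with a median of 0.12 (0.48 with slide as a block, adjusted p = 0.000914) and an adjusted p of 0.111, or 0.693 with an estimated correlation. Their median was -0.067 without wild type replicate 3 and -0.017 without knockout replicate 3, and the list was called higher without wild type replicate 1 (adjusted p = 0.0228), wild type replicate 2 (0.0427) or knockout replicate 1 (0.00635). The cyclin Ccnd2 was at 0.39 and Ihh at 0.66. Of 13 theca and interstitial markers 9 were lower, with a median of -0.090 (0.26 with slide as a block, 0.023 without wild type replicate 2, 0.042 without knockout replicate 3) and an adjusted p of 0.254, and the estrogen receptor Esr1 was at -0.43. Corpus luteum markers were lower in 11 of 17, with a median of -0.45 (-1.12 with slide as a block) and an adjusted p of 0.443. Without knockout replicate 2 the median was 0.088, and without knockout replicate 1 the list was called lower (adjusted p = 0.0320). Cyp2e1 was at -1.66 with a standard error of 0.75, or -0.76 without wild type replicate 1, and Cdkn1c at 0.55. Ovulation and cumulus genes had a median of -0.048 (-0.27 with slide as a block, 0.037 without knockout replicate 2, 0.020 with array weights) over 13 members, a mean of 0.022 and an adjusted p of 0.879. Tnfaip6, a gene of the expanding cumulus, was at 1.74 with a standard error of 0.73, or 1.04 without knockout replicate 3. Ptx3 was at 0.56, and ran from 0.33 to 0.89 over the arrays left out in turn.

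Immediate early genes, which respond within minutes to stimuli and to handling of tissue, had members on both sides. Of 17 measured members 12 were higher and 5 lower, with a median of 0.19 (0.19 with slide as a block) and a camera adjusted p of 0.111. For change in either direction, the mixed test of fry gave an adjusted p of 0.389. Without knockout replicate 1 the median was -0.088. The list was called higher without knockout replicate 2 (adjusted p = 0.000120) and with no filter on background (0.0371). With an estimated correlation the adjusted p was 0.693. Over all probes 0 members passed, and adjusted over the list alone 2 did, Nr4a1 as higher and Myc as lower, both with an adjusted p of 0.0185. The list median was 0.72 in knockout replicate 1 and between -0.35 and -0.025 on the other arrays.

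Markers of surface epithelium and mesothelium were lower in 14 of 16, with a median of -0.33 (-0.11 with slide as a block, adjusted p = 0.498) and a camera adjusted p of 0.00300. With an estimated correlation the adjusted p was 0.693. Lrrn4 was at -1.02 with a standard error of 0.32 and Gpm6a at -0.54 with a standard error of 0.25. Without wild type replicate 1 these 2 genes were at -0.67 and -0.30. The list had an adjusted p of 0.0541 without wild type replicate 1, 0.122 without knockout replicate 1 and 0.0983 with array weights. Lists of other tissues that a dissected ovary can carry were not called in the main analysis, but their calls changed between alternatives. Oviduct and ciliated cell markers were lower in 9 of 12, with a median of -0.32 (-0.023 with slide as a block) and an adjusted p of 0.0568. The list was called lower in 6 of 18 alternatives, among them the replicate block (adjusted p = 0.00812), without wild type replicate 1 (0.0235) and without wild type replicate 3 (0.00858). With an estimated correlation its adjusted p was 0.693. Ccdc153 was at -1.93, or -1.17 without wild type replicate 2. Rsph1 was at -0.52, and ran from -0.83 to -0.28 over the arrays left out in turn. Adipocyte markers had a median of -0.20 over 11 members (0.38 with slide as a block, 0.10 without wild type replicate 1) and an adjusted p of 0.158. On the shared slide alone, which holds 1 wild-type array, their median was 0.38. They were called lower without wild type replicate 3 (adjusted p = 0.0173), and with an estimated correlation the adjusted p was 0.693. Among them Thrsp was at -1.13 and Fabp4, a lipid-binding protein of fat cells, at -0.87, or 0.10 without wild type replicate 1. Smooth and skeletal muscle markers had a median of -0.24 over 11 members (-0.042 with slide as a block) and an adjusted p of 0.0842. The median was 0.025 without knockout replicate 2, and the list was called lower without wild type replicate 2 (0.0437), knockout replicate 1 (0.0182) or knockout replicate 3 (0.0457). For the muscle list the adjusted p with an estimated correlation was 0.693. Synpo2 was at -0.48 and Myh11, a smooth muscle myosin, at -0.41. Fibroblast and matrix genes had a median of -0.11 over 19 members (-0.18 with slide as a block) and an adjusted p of 0.133. The median was 0.12 without knockout replicate 2 and 0.042 with array weights, and the list was called lower without knockout replicate 1 (0.00937) or knockout replicate 3 (0.00872). For the fibroblast list the adjusted p with an estimated correlation was 0.693. Dcn was at -0.57, or -0.34 without wild type replicate 1, and Eln at -0.62, or -0.38 without knockout replicate 2.

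Blood and immune genes were higher on balance, and their lists were called at the preset correlation only. Macrophage and myeloid markers were higher in 16 of 20, with a median of 0.20 (0.32 with slide as a block, adjusted p = 0.202) and an adjusted p of 0.0235, with Cd68 at 0.76 and the scavenger receptor Marco at -0.58. Lymphocyte and NK cell markers were higher in 10 of 16, with a median of 0.044 (0.0043 with slide as a block, adjusted p = 0.358, and -0.014 with normexp background correction) and an adjusted p of 0.0298. Cd3g and Cd3d, which encode CD3 subunits of the T-cell receptor complex, were at 0.65 and 0.84. Genes of MHC class II and the interferon response were higher in 20 of 25, with a median of 0.13 (0.47 with slide as a block, adjusted p = 6.89e-05) and an adjusted p of 0.0274, with Iigp1 at 0.58 and Cxcl10 at 0.42. Erythroid markers were higher in 4 of 6, with a median of 0.97 (1.20 with slide as a block, adjusted p = 0.0715) and an adjusted p of 0.0235. The haemoglobin genes Hbb-b2 and Hba-a2 were at 1.48 and 1.28, or 0.77 and 0.65 without knockout replicate 2. The erythroid median was 1.71 in knockout replicate 2 and between -0.72 and -0.058 on the other arrays. For each of these 4 lists the adjusted p was 0.693 with an estimated correlation. Without wild type replicate 3 it was 0.848 for the interferon list, whose median was then -0.065, 0.285 for the erythroid list and 0.146 for the macrophage list. Without wild type replicate 2 it was 0.0960 for the macrophage list, 0.119 for the lymphocyte list and 0.0541 for the erythroid list. Leaving out knockout replicate 1 gave 0.848 for the macrophage list, 0.370 for the lymphocyte list and 0.404 for the interferon list, and leaving out knockout replicate 3 gave 0.190, 0.187 and 0.256 for the same lists. The erythroid list had 0.162 without knockout replicate 2. With no filter on background the adjusted p was 0.188 for the lymphocyte list and 0.478 for the erythroid list. With array weights it was 0.121 for the interferon list and 0.173 for the erythroid list, and with the replicate block 0.0503 for the lymphocyte list. Endothelial markers had a median of 0.087 over 18 members (-0.23 with slide as a block, -0.073 without knockout replicate 1), a mean of -0.017 and an adjusted p of 0.677. They were called higher without knockout replicate 2 (0.0360) and with array weights (0.0409), but not with an estimated correlation (0.910). Lyve1, a lymphatic marker, was at -0.68 and Cldn5 at 0.28, or -0.016 with slide as a block and 0.033 without knockout replicate 1.

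Cell cycle genes were higher in 22 of 27, with a median of 0.11 (0.32 with slide as a block, adjusted p = 0.00948) and a camera adjusted p of 0.0235, or 0.693 with an estimated correlation. Cenpf was at 0.97 with a standard error of 0.35, though well above background on only 1 wild-type array, and Ube2c at 0.22 with a standard error of 0.13. Oxidative phosphorylation genes were lower in 23 of 29, with a median of -0.071 (-0.16 with slide as a block, adjusted p = 0.000332) and an adjusted p of 0.0235, or 0.693 with an estimated correlation. The call was lost with normexp background correction (0.320), the deposited series table (0.0811), no filter on background (0.268), the replicate block (0.0503) and array weights (0.0983). Of the 4 measured subunits of succinate dehydrogenase, Sdhd was at -0.24, Sdhc at -0.21, Sdhb at -0.16 and Sdha at -0.076. Without wild type replicate 3 the adjusted p was 0.344 for the cell cycle list and 0.757 for the oxidative phosphorylation list. The cell cycle list also had 0.252 without wild type replicate 1 and 0.459 without knockout replicate 2, where its median was -0.080, and with array weights its median was -0.16 (adjusted p = 0.173). The oxidative phosphorylation list had 0.0541 without wild type replicate 2, 0.101 without knockout replicate 2 and 0.187 without knockout replicate 3.

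Of 51 measured genes near Selenbp1 on chromosome 3, 36 were lower, with a median of -0.049 (-0.030 with slide as a block) and an adjusted p of 0.280. Tmod4 was at -0.27 and Tdrkh at 0.74, or 0.30 without knockout replicate 3. In all, 9 of the 25 lists passed at the preset correlation, 0 with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.729, and apart from the 2 immediate early genes no list member passed when adjusted over its list alone.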

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

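Selenbp1 was lower in the knockout under every alternative tried, with log2 differences of -2.84 to -2.64 over the arrays left out in turn. Its adjusted p was above 0.05 with no filter on background (-2.75, adjusted p = 0.0824), slide as a fixed block (-2.74, adjusted p = 0.0792), the shared slide alone (-2.74, adjusted p = 0.347) and the replicate block (-2.75, adjusted p = 0.557). Over all alternatives the adjusted p ran from 0.00212 to 0.557. The blocks and the single slide leave fewer degrees of freedom, and without the filter 39429 probes were tested. The count of called genes, 1, was 0 with no filter, 0 with slide as a fixed block, 0 on the shared slide alone and 0 with the replicate block, 6 with array weights (Selenbp1, Nnt, Sik1, Serpinb1c, Gm4312 and LOC100044553), and 0 to 19 over the arrays left out. The count of called lists, 9, was 5 with array weights, 0 with an estimated correlation, 0 with fry and 5 to 8 over the arrays left out, with 5 without wild type replicate 3. The other alternatives gave 1 gene and 6 to 10 lists.

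No clear pairing by replicate number was seen. For samples of the same number, deviations from the group means correlated at -0.33, 0.30 and -0.027. Only for number 2 did each sample correlate best with its own number. Deviations from a group mean are tied to each other, so this check cannot exclude pairing. Of 1251 values of the other 70 named genes under the alternatives, 1238 kept their direction and side of the threshold and 3 passed it, all with array weights. Another 10 had the opposite sign. With slide as a fixed block and on the shared slide alone these were Cdo1 at 0.075, Sohlh1 at 0.047, Fabp4 at 0.17 and Cldn5 at -0.016. Over the arrays left out, Fabp4 ran from -1.39 to 0.10, the latter without wild type replicate 1, and LOC100045064 from -0.055, without knockout replicate 2, to 0.34. Leaving out 1 array moved 31 of these 70 genes by more than 1.5 times, and 9 of them were more than halved or turned, which the report gives beside each. The cause was not tested. No named gene changed sign under another scaling or background correction. Slide as a block raised the probes at an unadjusted p under 0.05 from 964 to 2389. The probes of Serpinb1c, Notch1, Cenpf, Tnfaip6, Ptx3 and Tdrkh were not well above background on all wild-type arrays, which limits how well the size of their differences is known.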

Other observations

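The tests of Nnt and of the luteal state of the ovaries were chosen after the results were seen, and those of Txnip, of the 9 lists and of the probes called without wild type replicate 3 after the pattern but before the value of the test. The ovaries differed from each other in several tissue signatures within each genotype. Knockout replicate 2 combined the highest erythroid median, 1.71, with the lowest medians of corpus luteum markers, -1.02, and of cholesterol genes, -0.66, each relative to the mean of 6 arrays. Wild type replicate 3 had the highest of both, 0.80 and 1.01. Oviduct and ciliated cell markers were highest in wild type replicate 2, at 0.76, and adipocyte markers in wild type replicate 1, at 0.75. Among members picked after their values were seen, Ovgp1, the oviductal glycoprotein, had a log2 difference of -3.05 (standard error 1.82), Cfd, an adipocyte protease, -2.56 (standard error 2.52), and Bhmt, a methyltransferase of methionine synthesis, -2.73 (standard error 2.16). None passed the threshold. The first principal component took 39.4% of the variance and ran from -41.6 in knockout replicate 2 to 41.7 in wild type replicate 3.

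The within-genotype spread of the corpus luteum list, an SD of 0.49 against a median of 0.051 for random lists of equal size and expression, lay at the 100th percentile of 10000 such lists. This is consistent with the hypothesis that the ovaries were taken at different luteal states, but 16 of the 25 lists reached that percentile, so the test does not single out luteal cells, and the labels give no stage of the cycle.

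The 9 lists called at the preset correlation may reflect variation between animals that the genes of a list share. Simulated sets with the estimated correlations and no genotype effect gave a median of 7 called lists, and 41 of 100 sets gave 9 or more. With the correlation estimated, 0 lists were called. Of the 10 splits of the 6 arrays into 3 and 3, 6 gave at least as many lists, the real split counted among them, and the highest other split gave 15. An effect of the knockout on any of these lists stays open, and 10 splits are too few for a share under 0.05.

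Nnt was higher in all 3 knockouts, and it is known that C57BL/6J mice carry a deletion within this gene. The difference on the shared slide was 1.45, with wild type replicate 3 at 0.99 and the knockouts at 2.28 to 2.58. Wild type replicates 1 and 2, on the other slide, were at 1.21 and 1.15. A shift common to all arrays of a slide would not by itself part wild type replicate 3 from the knockouts. But that slide holds 1 wild-type array, and Nnt was picked for its small p over all 6 arrays. The pick by itself sets this difference near the pooled 1.32, so slide was not taken as excluded. That reading was set after the value was known. A general rise of respiratory chain genes was argued against by the median of -0.071 in the oxidative phosphorylation list. A hypothesis is that the knockouts carry another strain's segment of chromosome 13 with an intact Nnt, although the labels give the same strain for both genotypes. The 20 other genes within 5 Mb had a median absolute t at the 82.4th percentile of windows elsewhere, between the levels set for and against it. Such a segment and a response of Nnt to the loss of Selenbp1 therefore cannot be told apart, and slide is not excluded.

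Without wild type replicate 3, 18 probes besides that of Selenbp1 passed the threshold, 17 of them lower in the knockout, among them Prm2, Msx2, Alox12b, Dnase1 and Slc16a8, named after their values were seen. On these probes wild type replicate 3 lay at a median share of -0.00628 of the distance from the knockout mean to wild type replicates 1 and 2, and 15 of the 18 shares were under 0.25. A share over 0.75 was to speak for genotype and one under 0.25 for slide. The share lay under the level set for slide. The probes were picked without the values of wild type replicate 3. But the pattern itself is a rise from 1 to 19 called genes when that array was left out. Of these 18 probes, 0 passed on all 6 arrays. Such a rise needs wild type replicate 3 to lie apart from replicates 1 and 2, so a low share was partly built in. The share also rests on 1 array. It was therefore not taken to speak for or against slide or genotype, a limit set after the share was known. With 1 wild-type array on slide 2, slide, genotype and anything else shared by the animals on slide 1 cannot be told apart for these probes.

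Txnip lies 1617 kb from Selenbp1, and a hypothesis was that a segment of another strain kept around the targeted gene may lower it. The 178 other genes within 5 Mb, with Txnip itself left out after the first result was seen, had a median absolute t at the 74.9th percentile of windows elsewhere, against the 77.5th with Txnip counted. Of them 6, or 3.37%, had an unadjusted p under 0.05, against 3.95% of all probes. The percentile lay between the levels set for and against the segment, so the test left this open. For the number of called genes, 2 of the 10 splits of the arrays gave at least 1, with 1 in the real split and 259 in the highest other, which set wild type replicates 1 and 2 and knockout replicate 2 against the rest. That split was picked as the highest, and what sets its samples apart was not tested. The oocyte list, named here after its values were seen, followed the same split. Its median was 0.33 and 0.37 in wild type replicates 1 and 2 and 0.38 in knockout replicate 2. It was -0.36 in wild type replicate 3 and -0.25 and -0.46 in knockout replicates 1 and 3. The other 2 splits that pair wild type replicates 1 and 2 of slide 1 with a knockout, replicate 1 or 3, gave 0 genes each. With slide as a block, genotype gave 0 genes. The splits are too few for a share under 0.05.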
